A study of Mus musculus with 7 samples.

How the data were processed

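Hearts of newborn mice, 3 WT and 4 edKO, were collected whole. Per the labels' protocols, total RNA of separate biological replicates was prepared with the RNeasy kit, cDNA was made and amplified from 1 to 10 ng with the Ovation RNA-seq System v2, and single reads of 61 nt were sequenced on a HiSeq-2500. The submitters' processing notes name cutadapt, RSEM 1.3.1, limma and the build GRCm38. The order of steps, the annotation release and the filter are not given in the sources used here. The sex and litter of the mice are not in the labels, and the groups share no replicate number.

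The deposited signal values are normalised reads per 1000000 in a single table of 13788 genes and 7 libraries. It holds no fold changes or p-values of the authors. Tested on the values, each equals the reads plus 0.5, divided by an effective library size and multiplied by 1000000. By that formula 100% of the 96516 values came out as whole reads, within a tolerance of 1e-06, although RSEM estimates need not be whole. The effective sizes divided by the totals give factors whose product over the 7 libraries is 1. Each listed gene had at least 1 recovered read per 1000000 of the library total in 3 or more libraries, so genes below that are not analysed here. Because the deposited normalisation sets the libraries to a common scale, a change shared by most transcripts would not be visible. The recovered totals ranged from 12108464 to 24912403 reads. Amplified reads without molecular identifiers are not independent molecules, so floors cover counting error only.

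Gene identifiers were matched to GENCODE release M21 for GRCm38, from which positions are taken. It held 13721 of them (99.5%), and 82 had no symbol. Reads were unlike between every pair of libraries (chi-square per degree of freedom 9.07 to 56.1), so none was a duplicate. For each named gene the share of 61-nt windows of its transcripts that also occur in transcripts of another gene, on either strand, was computed.

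The design set limma for normalised values and edgeR for counts, and the values were normalised. The main test was limma 3.58.1 in R 4.3.3, on log2(value + 1) with a mean-variance trend, all 7 libraries, no covariate, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A fold change is on the log2(value + 1) scale and understates the change of low genes. The 44 gene lists were tested with camera at a preset correlation of 0.01, 41 of them having at least 5 measured members. Fry tests whether the genes of a list move, on balance, in a single direction and does not compare the list with other genes. Rxra, Rxrb and Rxrg were also tested by exact permutation over all 35 assignments, by the absolute difference.

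The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 3 receptor genes, the 8 largest rises and falls among called genes at or above the median level whose groups do not overlap, up to 8 called fatty acid oxidation genes, up to 4 called genes of each other list that passed its test or held 2 or more calls (the 2 most abundant members where none was called), and up to 2 called genes of the remaining lists. It left out predicted genes and pseudogenes and gave 83 genes, some of which are not reported here. Echs1, Pnpla2, Lpl, Mcm5, Ccne2 and Ccnb2 were named after their values were seen, to complete counts.

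The other settings tried were pseudocounts of 0.1 and 5, a mean value of at least 1, genes above the lower quartile, no trend, a robust variance, library weights, quantile normalisation, median centring, Xist as a covariate, leaving out each library, a 1.5-fold minimum, camera with an estimated correlation, fry, and lists without shared members. Added after seeing the data were edgeR 4.0.16, DESeq2 1.42.0 and limma voom on the recovered reads, reads thinned to the smallest library, and removal of genes within 10 Mb of Rxra or Rxrb. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

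The fits were tested on simulated data, with read counts for the 13788 genes drawn from the real means, dispersions and library sizes and 200 genes changed. For the comparison of edKO with WT, limma recovered 31.3% of the genes changed 1.5-fold, 73.1% of those changed 2-fold and 87.9% of those changed 4-fold, with 12 false calls among 140. DESeq2 gave 27 false calls among 162, edgeR 12 among 141 and voom 6 among 129. With no gene changed limma called 2.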

Results

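RNA was sequenced from whole hearts of newborn mice (postnatal day 0) of the C57BL/6 strain. Wild-type hearts (WT, n = 3, replicates 1, 2 and 28) were compared with hearts in which the retinoid X receptor genes Rxra and Rxrb were deleted in cardiomyocytes (edKO, n = 4, replicates 5, 6, 15 and 33). Retinoid X receptors are nuclear receptors that bind DNA together with partners such as the PPAR and LXR receptors. The title of the study places the samples in work on a fatty acid of maternal milk and the metabolic maturation of the heart, and the comparison asks which cardiac transcripts depend on these receptors at birth. The table held 13788 genes. The reads recovered from it came to 13497846, 13954528 and 12968266 in WT replicates 1, 2 and 28, and to 12108464, 16310697, 16836663 and 24912403 in edKO replicates 5, 6, 15 and 33. A floor of 3 reads lay between 0.122 and 0.262 normalised reads per 1000000, for counting error only. Levels are given as normalised reads per 1000000 with the SD, for n = 3 WT and n = 4 edKO throughout.

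The targeted genes were examined first. Rxra (chromosome 2, 27676440 to 27762957 on GRCm38) stood at 61.6 ± 1.99 in WT and 66.1 ± 6.74 in edKO (limma, log2 difference 0.10, adjusted p = 0.63; exact permutation p = 0.314). Rxrb (chromosome 17, 34031812 to 34038399) stood at 48.2 ± 3.18 and 38.9 ± 4.00, with every edKO library below every WT library, and did not pass the test (log2 difference -0.31, limma adjusted p = 0.139; exact permutation p = 0.0571). Without edKO replicate 33 its adjusted p was 0.044, within a range of 0.044 to 0.383 over the fits that left out 1 library. Rxrg, the third receptor of the family and not a target of the deletion, fell from 2.86 ± 0.522 to 0.878 ± 0.441 (limma adjusted p = 0.029; exact permutation p = 0.0286, the smallest that 35 assignments allow). Its call was lost on leaving out any WT library, edKO replicate 5 or edKO replicate 15 (adjusted p 0.068 to 0.147). The values are totals over whole genes, the sources used here do not give the deleted exons, and whole hearts hold other cells that keep both genes. Rxra and Rxrb levels therefore neither bear out nor contradict the genotype labels.

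Of the 13788 genes, 580 differed between edKO and WT by limma at an adjusted p under 0.05, 287 of them higher and 293 lower in edKO. Among these, 75 were at least 2-fold higher and 91 at least 2-fold lower. The groups did not overlap for 2406 genes (17.5%, against 5.71% by chance), and these included all 580. The genes with the steepest falls among those at or above the median level included Acot1, Scd4, Acot2, Acsl1, Hsdl2, Pdk4 and Slc25a20. The steepest rises were in Nppb, Baiap2, Neat1, Fkbp5, Klf15, Ctgf, Hif3a and Art3. Of the 580 genes, 180 were called in each of the 7 fits that left out 1 library, 66 higher and 114 lower. The count was 249, 222 and 252 without WT replicates 1, 2 and 28, and 364, 624, 345 and 1177 without edKO replicates 5, 6, 15 and 33. On the recovered reads it was 534 with edgeR (523 shared with the limma calls), 429 with voom and 1059 with DESeq2. With limma it was 370 without the mean-variance trend, 364 with Xist as a covariate and 1284 with library weights.

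**Figure D1:**
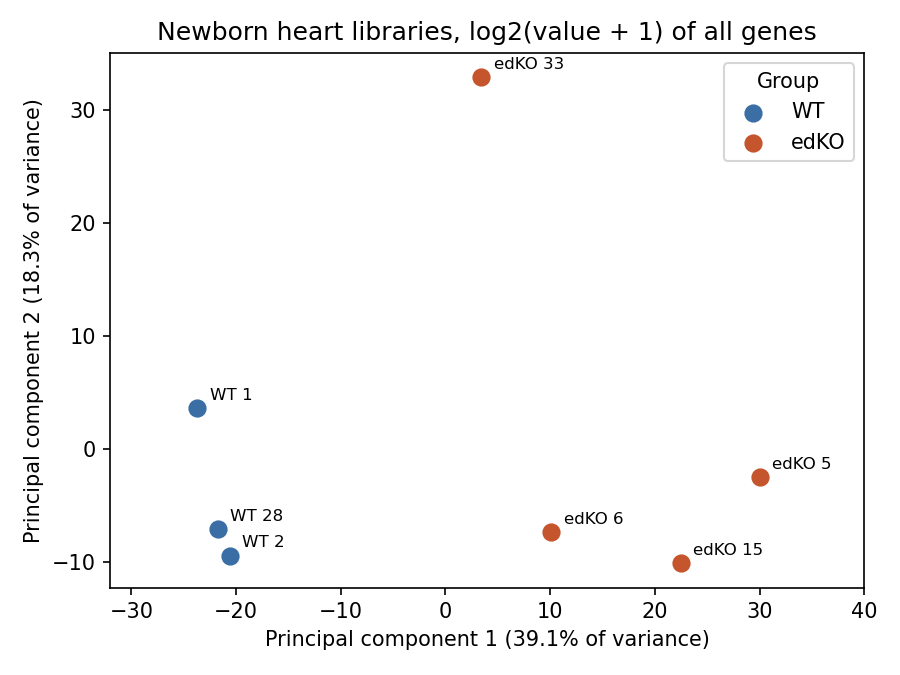
Principal components 1 and 2 of the log2 values of all genes (39.1% and 18.3% of the variance), 1 point per library, WT in blue and edKO in orange. The 3 WT libraries lie at -23.7 to -20.6 on component 1 and the edKO libraries at 3.42 to 30.0, while edKO replicate 33 stands apart on component 2 at 32.9.

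Genes of mitochondrial fatty acid oxidation were mostly lower in edKO. Of 26 measured genes, 21 were lower in edKO, 1 was higher (Echs1, log2 difference 0.42) and 4 did not pass the test. Acsl1, which activates long-chain fatty acids to their CoA esters, fell 7.02-fold, from 735 ± 83.4 to 105 ± 18.1. Acot2, a mitochondrial acyl-CoA thioesterase, fell 7.21-fold, from 247 ± 9.13 to 34.0 ± 6.76. The carnitine shuttle genes Slc25a20 and Cpt2 fell 3.37-fold and 3.08-fold, and Acadvl, the very long-chain acyl-CoA dehydrogenase, fell 3.29-fold, from 735 ± 45.4 to 223 ± 22.9. Decr1, Mlycd and Etfdh fell 2.82-fold, 2.87-fold and 2.66-fold. The limma adjusted p of these 8 genes lay between 1.22e-06 and 1.52e-05, and all 8 kept their call whichever library was left out, as did 17 of the 22 called genes of the list. Adjusted over the list alone, 23 genes were lower and 1 higher. The list median was -0.92 on the log2 scale (camera adjusted p = 8.39e-34; adjusted p = 0.135 with an estimated correlation; fry adjusted p = 0.000747). Of the 61-nt transcript windows of Acot2 and Acadvl, 24.7% and 23.6% also occur in transcripts of other genes (mostly Acot1, and Dvl2, which overlaps Acadvl), so part of their reads is uncertain in origin.

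**Figure D2:**
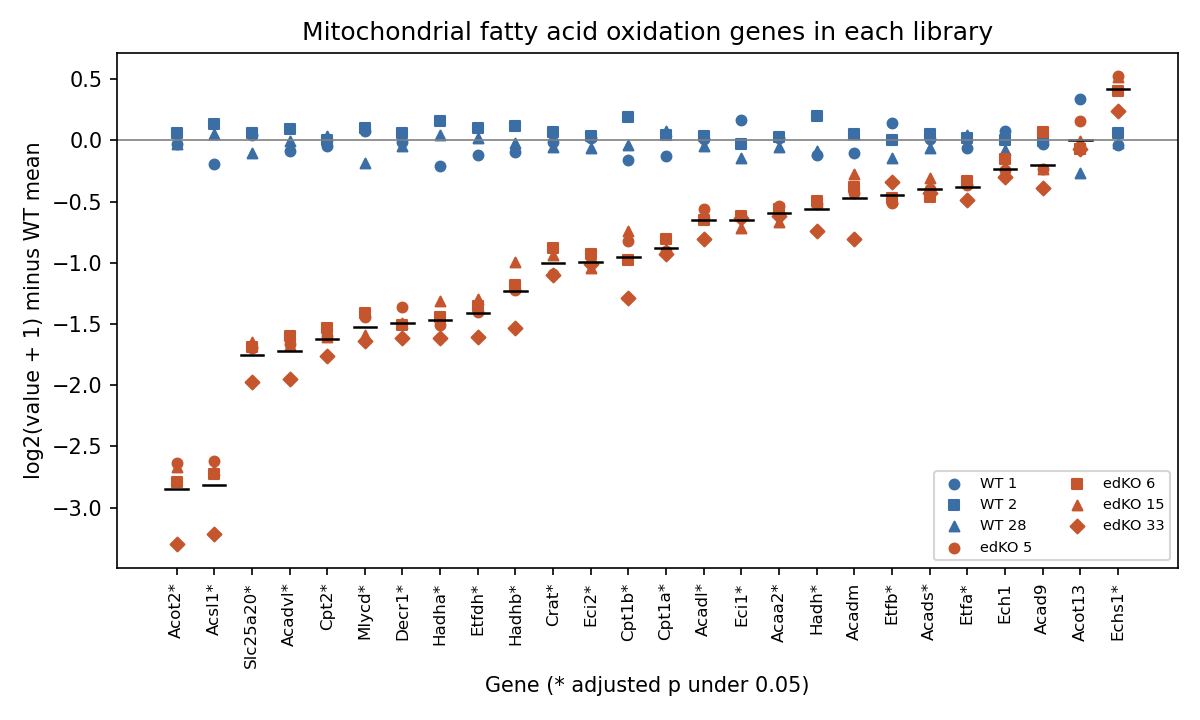
Log2(value + 1) of each mitochondrial fatty acid oxidation gene in each library, minus the WT mean, with 1 marker per library and a black line at the edKO mean. An asterisk marks an adjusted p under 0.05. For 21 of the 26 genes the edKO libraries lie below the WT libraries with a call, and Echs1 lies above.

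PPAR target genes, of which 20 also stand in other lists, fell as well: 19 of 27 measured genes were lower, none was higher and 8 did not pass. Plin5, a lipid droplet protein, went from 36.8 ± 3.00 to 1.02 ± 0.360, the mitochondrial carrier Ucp3 from 54.4 ± 4.81 to 1.45 ± 0.701, and the acyl-CoA thioesterase Acot1 from 139 ± 14.6 to 13.1 ± 3.69. Pdk4, a kinase that restrains pyruvate dehydrogenase, fell 3.77-fold. Of the 61-nt windows of Acot1, 17.2% occur in other genes, mostly Acot2. For 21 genes the test adjusted over the list alone gave a lower level. Their list had a median of -1.23 (camera adjusted p = 8.48e-30; adjusted p = 0.135 with an estimated correlation; fry adjusted p = 0.000798).

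In the list of fatty acid uptake, binding and lipid storage, 8 of 26 genes were lower and 2 higher. Fabp3, the fatty acid binding protein of heart muscle, fell 2.47-fold, from 2988 ± 367 to 1202 ± 61.2. Cidea, a lipid droplet protein, fell 3.57-fold, and Dgat2, an enzyme of triglyceride synthesis, fell 2.91-fold. The 2 higher genes were the lipases Pnpla2 and Lpl, with log2 differences of 0.89 and 0.70. Of the windows of Fabp3, 32.1% occur in other genes, mostly a pseudogene. Counts adjusted over the list alone were 9 lower and 5 higher. This list had a median of -0.16 (camera adjusted p = 0.0107; adjusted p = 0.856 with an estimated correlation), and the list was not called without edKO replicate 33 (camera adjusted p = 0.094) or once genes of several lists were removed (camera adjusted p = 0.461, median 0.03). In peroxisomal lipid metabolism 6 of 21 genes were lower and none higher. Catalase (Cat) went from 184 ± 6.21 to 91.8 ± 11.4 and Abcd3 from 91.1 ± 4.89 to 59.4 ± 3.82. Hsd17b4 and Pxmp4 had log2 differences of -0.47 and -0.57 and lost their calls without any single WT library (adjusted p 0.071 to 0.096, and 0.055 to 0.106, the latter with edKO replicate 15 among them). The median of the peroxisomal list was -0.19 (camera adjusted p = 0.00938, 0.856 with an estimated correlation, and 0.064 without edKO replicate 33).

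Of 8 ketone body genes, 2 were higher, 1 was lower and 5 did not pass. Bdh1, which interconverts the ketone bodies, rose from 3.48 ± 0.999 to 11.5 ± 2.07 and Oxct1, which starts ketone use, from 227 ± 26.1 to 355 ± 34.9. The ketone list had a median of 0.14, a mean of -0.20 and a camera direction of up (adjusted p = 0.549). Of the windows of Bdh1 and Oxct1, 10.5% and 10.9% occur in other genes. Oxct1 was not called without WT replicate 2 or 28 (adjusted p 0.053 and 0.051).

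Cholesterol biosynthesis genes and some LXR targets were lower. In cholesterol biosynthesis all 20 measured genes had a negative difference, 12 passed the test and 8 did not. Idi1 fell 2.29-fold, Sqle 2.45-fold and Insig1, a sterol sensor partner, 1.87-fold, with limma adjusted p between 0.000302 and 0.00131. With p adjusted over the list alone, 16 were lower. The median was -0.69 (camera adjusted p = 8.85e-17; adjusted p = 0.135 with an estimated correlation; fry adjusted p = 0.000996). Of LXR target genes, 4 of 12 were lower and none higher. Fasn, the fatty acid synthase, went from 115 ± 6.10 to 58.8 ± 5.19, Scd2, a fatty acid desaturase, from 282 ± 21.3 to 143 ± 29.1, Lpcat3 from 58.4 ± 3.86 to 29.4 ± 2.23 and Srebf1, a regulator of lipid synthesis, from 41.1 ± 3.35 to 24.8 ± 2.21. Scd4, a desaturase outside the lists, fell 8.67-fold. When adjusted over the list alone, 6 LXR targets were lower. Of the windows of Idi1, 24.5% occur in other genes. The LXR list median was -0.29 (camera adjusted p = 0.00127; adjusted p = 0.135 with an estimated correlation; fry adjusted p = 0.00318).

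Few genes of the respiratory chain were called. Only 580 of all 13788 genes were called, so lists of these sizes would hold few calls in any case. By limma, 0 of 37 nuclear genes of complex I, 0 of 19 of ATP synthase, 0 of 24 of the TCA cycle and pyruvate oxidation and 0 of 78 mitochondrial ribosomal protein genes were called, and 1 of 28 of complexes II to IV (Cox6b2, log2 difference -0.71, not called without any WT library or without edKO replicate 6 or 15, adjusted p 0.0503 to 0.125). List medians were -0.08, -0.06, -0.07, -0.10 and -0.07 in that order, and camera adjusted p for all but the ribosomal list 0.0723, 0.626, 0.232 and 0.130. At an unadjusted limma p under 0.05 the 4 lists without a call held 1, 0, 3 and 6 genes. Over all genes 2649 of 13788 lay under it. EdgeR and voom called 0 in each list, and DESeq2 called 0, 0, 1 and 3. Camera called the mitochondrial ribosomal list lower (adjusted p = 0.0111; adjusted p = 0.856 with an estimated correlation), with Mrpl42 at 174 ± 22.9 and 163 ± 4.54 and Mrpl12 at 174 ± 33.8 and 152 ± 19.2. The ribosomal list was not called without WT replicate 1 or edKO replicate 6 (camera adjusted p 0.872 and 0.0547). Complex I was called lower without WT replicate 2, WT replicate 28 or edKO replicate 33 (camera adjusted p 0.0153, 2.25e-05 and 0.0244), and complexes II to IV without WT replicate 2 or 28 (0.0320 and 0.00130). The 13 mitochondrially encoded mRNAs all had positive differences, and none passed by limma, edgeR, DESeq2 or voom or at an unadjusted p under 0.05. Their median was 0.31 (camera adjusted p = 0.0207; adjusted p = 0.856 with an estimated correlation). mt-Co1 stood at 25990 ± 5768 in WT and 33176 ± 4603 in edKO, and mt-Cytb at 11384 ± 2882 and 14249 ± 1997. Of the windows of mt-Co1, 46.1% occur in other genes. The call was lost without WT replicate 2, WT replicate 28 or edKO replicate 5 (camera adjusted p 0.242, 0.127 and 0.0855).

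Among 24 genes of glycolysis and lactate transport, 1 was higher and 3 lower. Slc2a1, the glucose transporter GLUT1, rose 2.17-fold, from 24.4 ± 2.58 to 54.4 ± 7.43, whichever library was left out. Aldoc, the lactate carrier Slc16a3 and Pfkl had log2 differences of -0.63, -0.66 and -0.32, and each lost its call on leaving out any WT library or edKO replicate 5 or 15, the last 2 also edKO replicate 6 (adjusted p 0.052 to 0.200). The median was 0.01, the mean -0.01 and the camera direction down (adjusted p = 0.875). In the hypoxia response list 3 of 18 genes were higher and none lower: Slc2a1, Ndrg1 (1.82-fold) and the mitophagy receptor Bnip3 (1.99-fold). Of the 61-nt windows of Bnip3, 41.2% occur in other genes. Those adjusted over the list alone numbered 6, all higher. The hypoxia list had a median of 0.15 (camera adjusted p = 0.0207; adjusted p = 0.595 with an estimated correlation).

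Several cardiomyocyte genes changed without a common direction in their lists. Nppb, which encodes the B-type natriuretic peptide, rose 5.26-fold, from 137 ± 28.4 to 746 ± 264. Myh7, the slow myosin heavy chain of the fetal ventricle, rose from 5658 ± 1249 to 13659 ± 2712, Ankrd1 from 658 ± 168 to 1449 ± 283 and Xirp2 from 20.4 ± 1.23 to 54.5 ± 24.0. The other 11 of the 15 fetal and load-responsive genes did not pass, and the list median was -0.15 while its mean was 0.25 and its camera direction up (adjusted p = 0.315). Myh7 was not called without WT replicate 28 (adjusted p = 0.055) and Xirp2 without any single WT library (0.060 to 0.076). Of the windows of Myh7, 16.8% occur in other genes, mostly Myh6. Of 20 mature cardiomyocyte genes, Ckmt2 was higher (229 ± 4.54 to 332 ± 15.7) and Hrc lower (log2 difference -0.52), with a list median of -0.02, a mean of 0.01 and a camera direction of down (adjusted p = 0.870). Hrc was not called without any WT library or edKO replicate 5 (adjusted p 0.053 to 0.095).

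Among 15 pan-cardiomyocyte genes, the transcription factor gene Nkx2-5 (chromosome 17, 26838664 to 26845009) fell from 80.1 ± 2.73 to 43.6 ± 1.29 (limma adjusted p = 0.000192), and Csrp3 rose from 833 ± 55.1 to 1290 ± 223. The pan-cardiomyocyte median was -0.04 (camera adjusted p = 0.393). Csrp3 was not called without any WT library or edKO replicate 5 or 15 (adjusted p 0.084 to 0.145). Of 10 atrial genes, Dkk3 and the potassium channel gene Kcna5 were higher (log2 differences 0.88 and 0.73; median -0.15, camera direction up, adjusted p = 0.682). Dkk3 lost its call without WT replicate 1 or 2 (adjusted p 0.053 and 0.065), and Kcna5 without any library other than edKO replicate 33 (0.053 to 0.139). Of 8 ventricular genes, the potassium channel subunit gene Kcne1 fell from 154 ± 20.8 to 71.1 ± 1.73 and Lrrc10 rose from 111 ± 7.57 to 246 ± 75.9, with a median of 0.05 and a camera direction of down (adjusted p = 0.841). Lrrc10 was not called without WT replicate 1 or 28 (adjusted p 0.060 and 0.051).

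**Figure D3:**
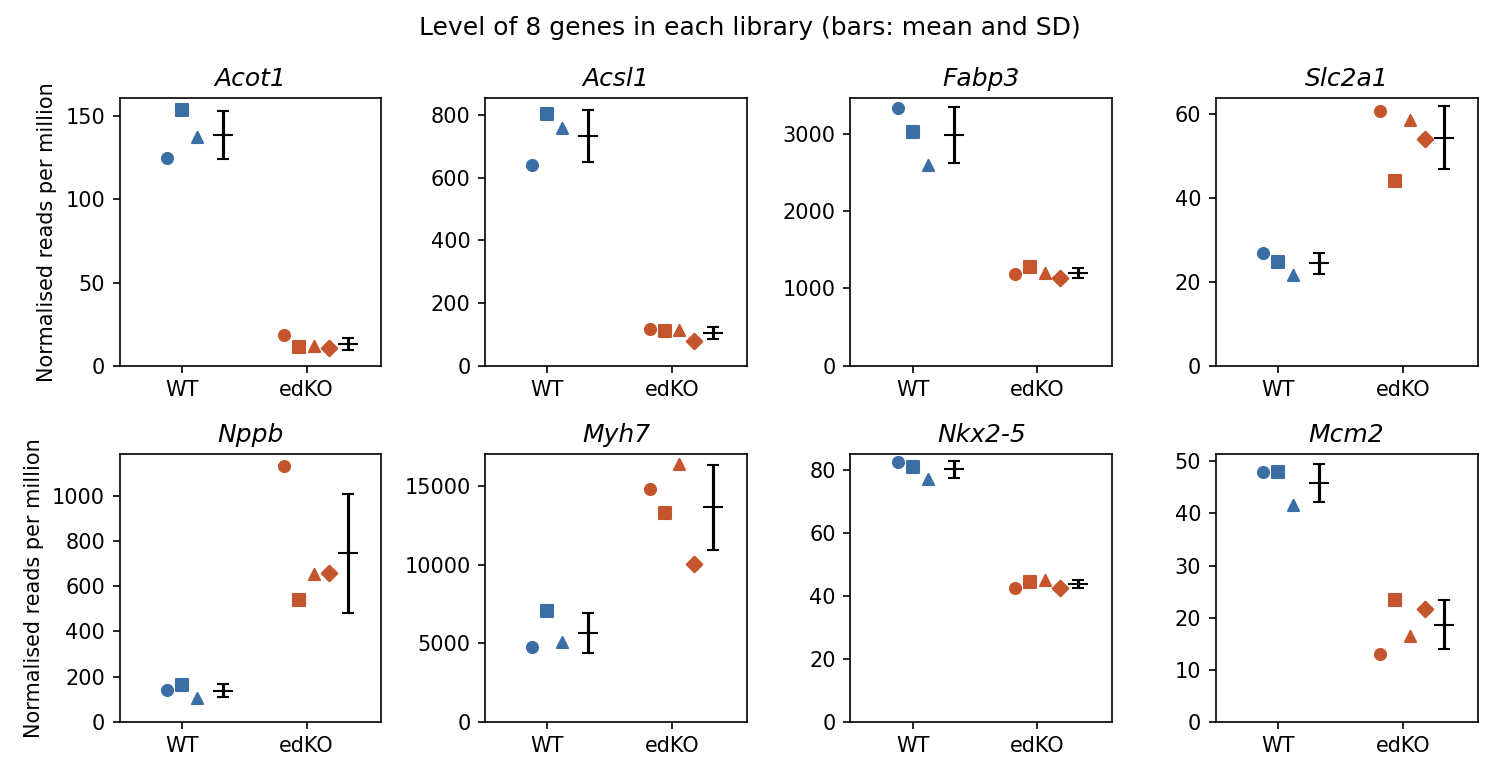
Normalised reads per 1000000 of 8 genes in each library (WT blue, edKO orange, 1 marker per replicate), with the mean and SD of each group in black and axes starting at 0. The edKO libraries lie below WT for Acot1, Acsl1, Fabp3, Nkx2-5 and Mcm2 and above WT for Slc2a1, Nppb and Myh7.

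The proliferation list split. The replicative helicase genes Mcm2, Mcm3, Mcm4 and Mcm6 fell 2.44-fold, 2.33-fold, 2.09-fold and 1.78-fold, and Mcm5 and the cyclin gene Ccne2 were also lower, while the mitotic cyclin gene Ccnb2 was higher (log2 difference 0.52). The other 18 of 25 genes did not pass. The proliferation list had a median of 0.07, a mean of -0.19 and a camera direction of down (adjusted p = 0.183). It was called lower without edKO replicate 33 (median -0.18, camera adjusted p = 0.0166), and Mcm6 was not called without WT replicate 1 or 28 (adjusted p 0.059 and 0.053). By p adjusted over the list alone, 10 were lower and 5 higher.

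Among 11 glucocorticoid-induced genes all had positive differences and 3 passed. Fkbp5, which encodes a steroid receptor co-chaperone, rose from 23.7 ± 4.43 to 75.3 ± 35.4, Per1 from 26.3 ± 3.53 to 60.02 ± 22.5 and Zbtb16 from 5.23 ± 3.07 to 19.2 ± 9.16. If adjusted over the list alone, 10 were higher. The glucocorticoid list had a median of 0.85 (camera adjusted p = 5.39e-08; adjusted p = 0.595 with an estimated correlation; fry adjusted p = 0.121). The list mean lay 1.53 above WT in edKO replicate 5, against 0.63, 0.94 and 0.44 in replicates 6, 15 and 33. Fkbp5 kept its call whichever library was left out; Per1 lost it without any WT library or edKO replicate 15 (adjusted p 0.069 to 0.116), and Zbtb16 without WT replicate 1 or 2 or edKO replicate 5, 6 or 15 (0.055 to 0.119). Of 16 clock genes, Per1, Per2 (log2 difference 1.49) and Arntl (0.73) were higher, with a median of 0.18 (camera adjusted p = 0.0817, 0.00539 without WT replicate 28 and 0.0278 without edKO replicate 33). Per2 was not called without WT replicate 1 or 2 (adjusted p 0.059 and 0.051), nor Arntl without any WT library or edKO replicate 5 or 15 (0.1001 to 0.169). The labels do not give the time of collection of either group, so a part of it in the glucocorticoid and clock differences was not tested. Outside these lists, Klf15, a metabolic transcription factor, rose from 16.3 ± 1.56 to 50.2 ± 21.6, Hif3a 2.66-fold and the non-coding RNA Neat1 3.10-fold. Each of the 3 lost its call without any WT library or edKO replicate 15 (adjusted p 0.052 to 0.129). Baiap2 rose 3.92-fold, Ctgf 2.67-fold and Art3 2.61-fold, each called whichever library was left out. Of the windows of Ctgf, 16.1% occur in another gene.

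Of 26 receptor partners and metabolic regulators only the coactivator gene Ppargc1a passed, at 88.2 ± 11.8 in WT and 130 ± 18.8 in edKO, and it lost its call on leaving out any library other than edKO replicate 33 (adjusted p 0.066 to 0.166). The regulator list had a median of 0.12 (camera adjusted p = 0.0350; adjusted p = 0.856 with an estimated correlation) and was not called without WT replicate 1 or 28 or edKO replicate 6 or 15 (camera adjusted p 0.0615 to 0.204). Of 7 measured genes of retinoic acid response and retinoid metabolism, Aldh1a2, which makes retinoic acid, was lower (44.2 ± 5.51 to 22.5 ± 6.12) and Dhrs3, a retinaldehyde reductase, higher (22.4 ± 1.07 to 34.2 ± 5.62), with a median of 0.10 (camera adjusted p = 0.342). Aldh1a2 was not called without any single WT library (adjusted p 0.056 to 0.084), nor Dhrs3 without any library other than edKO replicate 33 (0.055 to 0.134). Of 14 immediate early genes, Btg2 was higher (log2 difference 0.63), with a median of 0.13 (camera adjusted p = 0.0415; adjusted p = 0.856 with an estimated correlation). Btg2 lost its call without WT replicate 2 or 28 or edKO replicate 5 (adjusted p 0.053 to 0.10), and the list without WT replicate 28 or edKO replicate 5 or 6 (camera adjusted p 0.112, 0.0552 and 0.293). By limma, 0 of 18 genes of the mitochondrial and amino acid stress response and 0 of 16 interferon response genes were called, with medians of -0.06 and 0.17 (camera adjusted p = 0.956 and 0.0817). They held 7 and 2 genes at an unadjusted p under 0.05, where all genes gave 2649 of 13788. EdgeR and voom called 0 in both lists and DESeq2 1 and 0. The stress list had a mean of 0.03 and a camera direction of down. Camera called the interferon list higher without WT replicate 1 or edKO replicate 5 (adjusted p 0.00920 and 0.0202).

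Markers of other cell types gave few calls. Over all genes only 580 of 13788 were called, so lists this small would hold few calls in any case. By limma, 0 of 12 fibroblast, 0 of 12 endothelial, 0 of 10 smooth muscle and pericyte, 0 of 11 macrophage, 0 of 5 neutrophil, 0 of 5 thymus and T cell and 0 of 8 liver genes were called, with medians of -0.36, 0.13, 0.03, 0.05, 0.11, 0.46 and 0.22. At an unadjusted p under 0.05 they held 2, 2, 2, 2, 0, 0 and 1 genes, where all genes gave 2649 of 13788. DESeq2 called 0, 1, 2, 0, 0, 0 and 0, and edgeR and voom called 0 in each list. Smooth muscle and macrophage genes had means of -0.10 and -0.04 and a camera direction of down. Camera called the fibroblast list lower (adjusted p = 0.0350; adjusted p = 0.856 with an estimated correlation), but not without WT replicate 28 or edKO replicate 5 or 15 (0.153, 0.0849 and 0.151). The other 6 lists had a camera adjusted p of 0.117, 0.810, 0.906, 0.417, 0.231 and 0.368. Endothelial genes were called higher without WT replicate 1 or edKO replicate 15 (0.00808 and 0.0219) and thymus genes without WT replicate 2 (0.0227). Col3a1 stood at 2148 ± 315 and 1615 ± 601 and Postn at 1230 ± 102 and 1024 ± 335, and both were called lower without edKO replicate 33 (adjusted p 0.036 and 0.029). Of 10 erythroid genes 1 was higher (median 0.28, camera adjusted p = 0.186). Other single calls were Aldh1a2 among 8 epicardial genes (-0.20, 0.427), Dbh (log2 difference -0.87) among 5 nerve genes (-0.22, 0.223) and Tnni2, a fast skeletal muscle troponin (-1.19), among 5 skeletal muscle genes (-1.17, 0.00773, and 0.856 with an estimated correlation). The skeletal muscle list was not called without WT replicate 28 (camera adjusted p 0.0552). Epicardial genes were called lower and erythroid genes higher without edKO replicate 33 (0.0347 for both), the latter also without WT replicate 1 (0.0185). Dbh lost its call without any library other than edKO replicate 33 (0.051 to 0.147). Of 2 measured adipocyte genes Cidea was lower, and 0 of 7 lung epithelium genes were among those listed. Haemoglobin genes took 3.10 ± 0.689% of reads in WT and 3.76 ± 1.01% in edKO, and mitochondrial genes 9.70 ± 1.74% and 11.3 ± 0.966%. As signs of RNA quality, 0 of 78 cytosolic ribosomal protein genes were called (median 0.02, camera adjusted p = 0.368). They held 3 genes at an unadjusted p under 0.05, edgeR, DESeq2 and voom called 0, and without WT replicate 1 camera called the list higher (adjusted p 1.91e-06). Of 12 histone genes Hist1h1c was higher (log2 difference 0.97; median 0.05, camera adjusted p = 0.434).

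**Figure D4:**
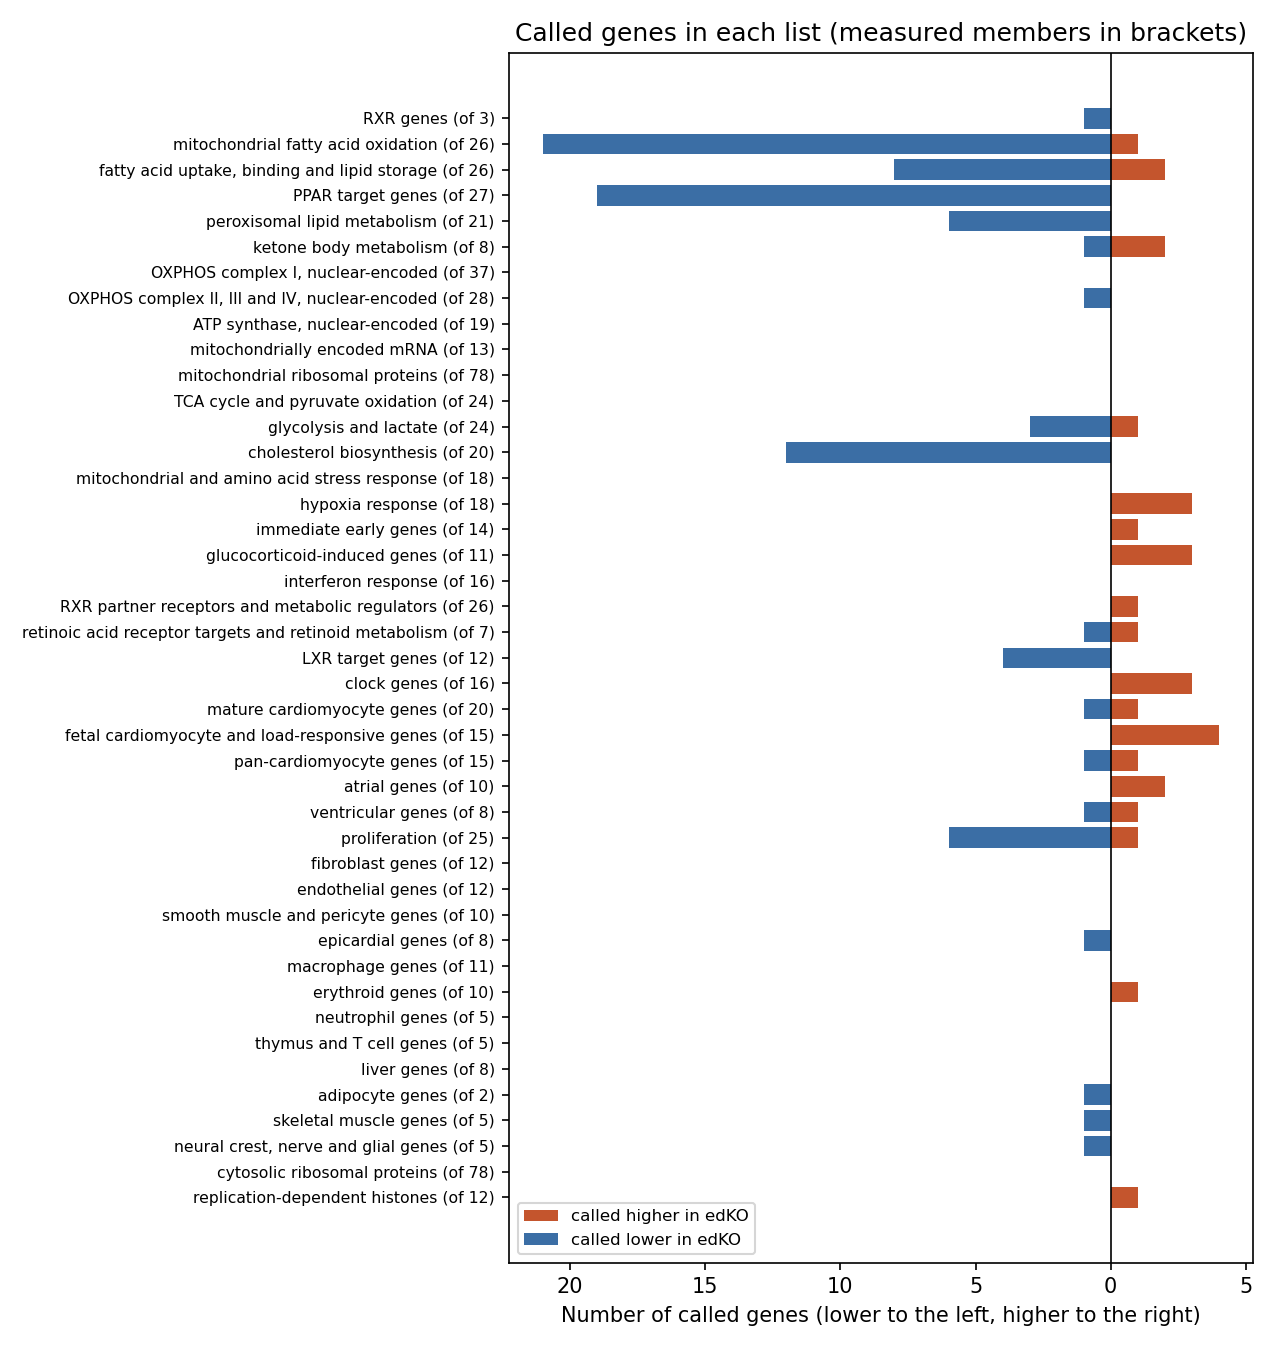
Number of genes called higher (right, orange) and lower (left, blue) in edKO in each list with measured members, whose number stands in brackets. Fatty acid oxidation (21 lower, 1 higher), PPAR targets (19 lower) and cholesterol biosynthesis (12 lower) hold the longest bars.

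Camera with a preset correlation called 14 of 41 lists, 5 higher and 9 lower. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05), and fry called 4, fatty acid oxidation, PPAR targets, cholesterol biosynthesis and LXR targets, all lower. Adjusted over the list alone, the counts not yet given rose to 2 higher and 3 lower in glycolysis, 2 and 2 in ketone body metabolism, 2 and 0 among immediate early genes, 3 and 1 in retinoid metabolism, 5 and 1 among clock genes, 4 and 1 among fetal and load-responsive genes, 2 and 1 among atrial genes, 1 and 1 among adipocyte genes, 0 and 4 among skeletal muscle genes and 0 and 2 among the receptor genes. In the lists left they equalled the counts over all genes.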

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

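Of the tests of explanations in this part, only the one that thinned the reads was set out before its result was seen. Single libraries were compared within the 4 edKO libraries for 127 values (named genes, list means and depth), and 6 had a library whose gap to its nearest neighbour was too large a part of the range. Chance gives about 1 in 20, which is about that number. In edKO replicate 5, Fkbp5 stood at 128 against 59.6 in the next library, Art3 at 319 against 187 and Acot1 at 18.6 against 11.6. In edKO replicate 33, Dgat2 stood at 22.1 against 33.1, and the list means of fatty acid oxidation at 7.25 against 7.45 and of ketone body metabolism at 5.66 against 5.71 on the log2 scale. The WT group of 3 was too small for this comparison.

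Library edKO 33 stood apart from the other edKO libraries, with a mean correlation across genes of 0.976 with the other 3, where each of those had 0.979 to 0.981 with its own other 3, and leaving it out raised the calls to 1177. Its greater depth did not account for this, because after thinning all libraries to a common total the mean correlation was 0.975, still below the others. The fatty acid oxidation genes showed no sign of incomplete loss of receptor function in this library. The mean of all 26 listed lay -1.15 from WT there, against -0.95, -0.94 and -0.94 in replicates 5, 6 and 15. A different mix of tissue, considered below, could also lower these genes, so they do not exclude incomplete loss. For the other 558 called genes it stays open: the median change in the direction of the call was smallest in replicate 33, 0.62 against 0.90, 0.69 and 0.76, which is within 1 SD of the other 3 (0.105) of the next library, and these genes were called in a fit that included it. All called lower genes had a median of -0.68 there (-0.87, -0.70 and -0.78 in the others) and all called higher genes 0.59 (0.94, 0.70 and 0.75). Rxrb stood at 44.0 in replicate 33, against 34.2, 38.5 and 38.7 in replicates 5, 6 and 15, and Rxrg at 1.45 against 0.741, 0.934 and 0.389. Both were nearest to WT in replicate 33, while Rxra was the lowest of the edKO libraries there (59.5). Totals over whole genes do not show the deletion, so these levels cannot decide the question. A lower share of cardiomyocytes was tested by whether the markers of all other types were highest in this library. This held for 7 of 11 lists, among them endothelial, fibroblast, smooth muscle, epicardial and macrophage genes. Erythroid genes lay at -0.12 relative to WT where the other edKO libraries lay 0.19 to 0.58 above, and neutrophil and thymus genes were lowest too (-0.26 and -0.34). Blood and thymus content can vary apart from the cardiomyocyte share, so these lists cannot decide the question. The pan-cardiomyocyte mean lay 0.0174 above WT there, against -0.0665, -0.145 and -0.0301 in replicates 5, 6 and 15. A lower share was therefore neither shown nor excluded. The test was first set out for any other mix of cells, on fewer lists, and was narrowed and then widened to all such lists after its result. A change in fibroblasts (0.17 above WT against -0.57 to -0.19), epicardium (0.34 against -0.48 to -0.21) or blood stays open. A larger share of atrial tissue is a candidate explanation for part of this. Atrial genes lay 0.59 above WT there (-0.48 to 0.11 in the others) and ventricular genes -0.13 (0.00350 to 0.06). However, WT replicate 28 had as low a ventricular mean (-0.13) and an atrial mean of 0.27, above the other edKO libraries. Of the 10 atrial genes, 3 also stand in the fetal and load-responsive list. The mean of that list was highest in replicate 33 too, at 0.50 against 0.38, -0.09 and 0.20 in replicates 5, 6 and 15. Litter and time of collection, which the labels do not give, were not tested.

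The count of 580 genes was reached in 1 of the 35 splits of the libraries into 3 and 4, the real one. That is the smallest share that 35 splits can give. It argues against chance for the count, but so few splits cannot exclude it. The highest other split gave 360. That other split set edKO replicates 5, 6 and 15 against the rest and so differs from the real one only in edKO replicate 33. The remaining splits called at most 5 genes each. The number of lists called by camera was as large or larger than the real 14 in 22 of the 35 splits, with up to 20, so chance is not excluded for the number of lists.

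Nkx2-5 fell to 0.545 of its WT level (95% limma interval 0.479 to 0.619), and the 4 edKO libraries lay between 0.531 and 0.561. Fewer cardiomyocytes are argued against by the other 14 pan-cardiomyocyte genes, whose median change was -0.0285 with an SD of 0.22. A candidate explanation is a single inactive copy of the gene, as a Cre driver inserted there would give. The interval includes 0.5, but the labels name no driver. Regulation of Nkx2-5 by the receptors gives no other value to test and stays open. Nkx2-5 and Fkbp5 also lie within 10 Mb of Rxrb, and Dbh within 10 Mb of Rxra. Of 311 genes around Rxrb 6.11% were called, against 4.16% elsewhere, and of 222 around Rxra 4.95% against 4.19% (one-sided Fisher p = 0.0666 and 0.332). Of 334 genes around Nkx2-5 5.69% were called, against 4.17% elsewhere (one-sided Fisher p = 0.113). After Benjamini-Hochberg adjustment over these windows the Fisher p were 0.169 for Rxrb, 0.332 for Rxra and 0.169 for Nkx2-5. For Nkx2-5, Fkbp5 and Dbh an effect of linkage to Rxrb or Rxra was not tested.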

How the results depend on the processing

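The tests on recovered reads, the thinned reads and the removal of linked genes were chosen after seeing the data. The 580 calls (287 higher, 293 lower) stayed within 1.5 times under both pseudocounts, both filters, a robust variance, quantile normalisation, median centring, a 1.5-fold minimum, edgeR, voom (all calls), thinning and removal of linked genes. They were 370 without the trend (160 higher), 1284 with library weights (646 and 638), 364 with Xist as a covariate (174 and 190) and 1059 with DESeq2 (565 and 494), and voom gave 185 higher. Leaving out a library gave 222 to 1177 genes, 95 to 585 higher and 127 to 592 lower. The library weight was lowest for edKO replicate 33 (0.429). Fewer samples are part of each fit without a library by construction; for the other changes the cause was not tested. The list calls, 14, became 0 with an estimated correlation and 4 with fry. Rxrb was called lower with library weights (-0.35, adjusted p = 0.034) and without edKO replicate 33 (-0.37, adjusted p = 0.044), and leaving out a library gave -0.37 to -0.25. Of 1816 comparisons of named genes, 1637 kept direction and call, 174 lost the call, 4 gained it and 1 reversed, Mrpl42 without WT replicate 1 (0.0164, with -0.166 the lowest on leaving out a library; never called). Of 934 comparisons of lists, 828 kept direction and call, 55 lost the call, 22 gained it and 29 reversed the direction of the test, all 29 in lists called in neither fit. Those lists had the following medians, lowest and highest, on leaving out a library: complex I -0.176 and 0.0263, complexes II to IV -0.115 and 0.0517, ATP synthase -0.140 and 0.0560, glycolysis -0.0739 and 0.0611, stress response -0.122 and -0.0234, mature cardiomyocyte -0.106 and 0.0353, fetal and load-responsive -0.184 and -0.0176, atrial -0.377 and 0.0367, ventricular -0.0700 and 0.0731, smooth muscle -0.0544 and 0.0948, macrophage -0.0489 and 0.0969, and cytosolic ribosomal -0.0654 and 0.131. Directions also reversed above the lower quartile of level for glycolysis (median 0.0121), stress response (-0.0313) and macrophage genes (0.0546), at a mean of at least 1 for stress response (-0.0502), with quantile normalisation for glycolysis (0.0335), with library weights for mature cardiomyocyte (-0.00570) and atrial genes (-0.321), and by fry for ketone genes (0.135). The cause of these reversals was not tested. The alternative of the authors' own adjusted p was not run, because the table used here holds none. No paired analysis was run, because the groups share no replicate number and the labels do not give the litters. In simulated data with these library sizes and replicate numbers, 31.3% of 1.5-fold changes were recovered.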

Other observations

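The lists in this part were written after the values had been seen, so their tests are descriptions of these libraries. Genes of branched-chain amino acid breakdown were higher in edKO for 5 of 23 measured genes and lower for 0 (limma, adjusted p under 0.05), and 18 of 23 had a positive difference. Bcat2, the mitochondrial branched-chain aminotransferase, rose from 64.9 ± 5.79 (SD, n = 3 WT) to 137 ± 19.6 (n = 4 edKO) and Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, from 31.5 ± 4.00 to 64.8 ± 4.84. Aldh6a1 rose from 92.6 ± 6.93 to 193 ± 48.0, Acadsb from 70.1 ± 4.505 to 113 ± 15.1 and Ppm1k, the phosphatase that activates the dehydrogenase, from 32.6 ± 2.70 to 56.7 ± 13.9. The list median was 0.23 (fry p = 0.0170; p = 0.154 by camera with an estimated correlation; exact permutation of the list mean, p = 0.0571), and the list mean lay 0.42, 0.34, 0.37 and 0.11 above WT in edKO replicates 5, 6, 15 and 33.

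Of 31 genes of DNA replication 11 were lower, 0 were higher and the rest did not pass, and all 31 had a negative difference (median -0.55; fry p = 0.0110; p = 0.0730 by camera with an estimated correlation; exact permutation of the list mean, p = 0.0571). Besides the Mcm genes, Cdt1 fell from 15.5 ± 1.10 to 7.17 ± 2.07, Cdc6 from 7.46 ± 1.199 to 3.11 ± 0.731 and Uhrf1 from 32.8 ± 3.22 to 14.9 ± 4.24. The replication list mean lay -0.99, -0.56, -0.75 and -0.31 from WT in edKO replicates 5, 6, 15 and 33. Of 24 mitotic genes, 3 were higher (Kif20a, Ccnb2 and Ube2c), 0 lower and all 24 had a positive difference (median 0.32), but the list passed none of its tests (fry p = 0.126; p = 0.234 by camera with an estimated correlation; exact permutation p = 0.143). The mitotic list mean lay 0.79 above WT in edKO replicate 33 and 0.09, 0.14 and 0.43 in replicates 5, 6 and 15.

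Xist stood at 167 in WT replicate 1 and at 441 and 179 in edKO replicates 5 and 6, and at 1.93 or less in the other 4 libraries, which held the Y-linked gene Eif2s3y at 72.4 to 92.9. By these levels WT replicate 1 and edKO replicates 5 and 6 were female and the other 4 libraries male. Xist as a covariate therefore stood largely for sex, and leaving out WT replicate 1 removed the only female WT library.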
